A study of Mus musculus with 12 samples.

How the data were processed

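Skeletal muscle RNA of C57Bl/6 mice was measured on 12 Affymetrix arrays, 4 each for chow, 5 days and 42 days of high-fat diet. The deposited values are RMA signals per probe set on the log2 scale; RMA is named in the labels with no version or software, and the log2 scale follows from the range and the near-equal quartiles of the values. Of 45098 probe sets, 61 were controls, 34945 carried 1 gene symbol, 932 several and 9160 none. Through their Entrez identifiers 34741 probe sets matched the reference gene table, 204 did not, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 12 arrays, which left a choice for the 9010 genes with more than 1; controls and probe sets with several symbols or none were left out, and no filter was set on dim genes. No genome coordinates were used. Arrays have no read depth, and their number limits the precision.

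Group means were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays (eBayes with a constant prior variance, 9 residual and 5.88 prior degrees of freedom), and 3 contrasts were tested two-sided: 5 days against chow, 42 days against chow, and 42 against 5 days. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and a gene counted as changed at an adjusted p under 0.05; a moderated F-test asked for any difference between the 3 groups. In the text, errors after ± are SE for log2 fold changes and SD for group values, folds are 2 to the size of the log2 fold change, and p-values of single genes come from limma. Gene groups came from 36 lists of pathways and cell type markers (816 genes listed, 759 measured), tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists; the correlation estimated per list and the test fry were alternatives. Camera compares a list with other genes, and fry asks whether its members move 1 way. The relation of the 5-day to the 42-day changes was compared with 100 simulations of unchanged groups that shared the chow arrays, and with the chow arrays split between the times.

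Lists, tests and the rule for named genes were fixed before the data were examined. The rule took, for each contrast, up to 8 rises and 8 falls with the largest changes among genes past the test (clone names left out), for each list up to 4 members with the smallest p in the list's direction where the list was past its test and up to 4 members past the test themselves, and a panel of 16 measured metabolic genes; of these, the text names all rises, falls and panel genes and 1 to 4 of each list's members. Alternatives fixed at the same time were quantile normalization, centring each array on its median, leaving out the 40% dimmest genes, the mean of a gene's probe sets or its most variable one, every probe set, array weights, a trended and robust prior, a fit of the 8 arrays compared, the replicate number as a block, an adjusted p under 0.1, ranks in camera, and leaving out each array in turn. Cyclic loess between arrays, the mean 3-prime to 5-prime difference of 4 control transcripts as a covariate, and the mean of the adipocyte markers as a covariate were added after the data were seen, as were lists of liver and tendon transcripts. Replicate numbers did not pair the arrays as a whole: 3 of 12 pairs of the same number correlated over 0.1, and 4 of 12 arrays correlated best with their own number. Those 3 were the pairs of replicate 1 (0.208, 0.215 and 0.221), so a factor shared by its arrays is not excluded.

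The procedure was tested on simulated data with 18193 genes, 50 of them changed at each size. A log2 change of 0.25 was recovered in 46%, 22% and 42% of genes in the 3 contrasts, a change of 0.5 in 96%, 94% and 100%, and changes of 1 and 2 in 100%; of the called genes 5.52%, 3.66% and 7.57% were false. A list shifted by 0.15 was called in 40 of 40 simulations, and 7 of 1400 tests of other lists were called. All simulated genes varied independently and held no trend with signal. In the real data the correlation estimated within the extracellular matrix list was 0.627. The simulated shares of false calls, for genes and lists, therefore do not carry over to the real data.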

Results

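Transcript levels were measured in skeletal muscle of C57Bl/6 mice with biotin-labelled cRNA on 12 Affymetrix arrays. Of these, 4 came from mice kept on chow, in which fat gave 13% of calories, and served as the control at both times. Another 4 came from mice switched at the age of 6 weeks to a high-fat diet, in which fat gave 46% of calories, and sampled after 5 days. The last 4 came from mice given that diet for 42 days. The values were log2 RMA signals of 45098 probe sets, which stood for 18193 genes, and ran from 3.67 to 15.46. The array medians averaged 7.67 ± 0.019 in the chow group, 7.61 ± 0.017 at 5 days and 7.67 ± 0.021 at 42 days (SD, n = 4 arrays per group). The number of arrays limits the precision. The first principal component held 26.6% of the variance, and the 42-day arrays lay on it between -16.2 and -6.92, below the other 8 arrays, of which the lowest was at -3.09. The second component, with 21.2%, parted the chow arrays (6.32 to 11.8) from the 5-day arrays (-12.2 to -4.16). Serpina1b, Apoa1, Mup3, Acly, Tkt, Malat1, Dlat, Lmcd1, Angptl4, Saa2 and Eif4ebp1 were read by probe sets whose names mark possible cross-hybridisation. The labels do not give the sex of the mice, the muscle, the age of the chow mice at sampling, any batch, or whether replicates were separate animals, so the p-values measure only the spread between samples.

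The first comparison asked which muscle transcripts differed after 5 days on the high-fat diet, in a series about insulin resistance. Fasn, the fatty acid synthase, fell from 11.88 ± 0.77 on chow to 9.72 ± 0.38 (log2 signal, SD, n = 4), or 4.45-fold lower. Its log2 fold change was -2.15 ± 0.28 (± SE), with adjusted p = 0.00669 by limma. Fabp3, the fatty acid-binding protein of muscle, rose 1.34-fold (0.42 ± 0.057, adjusted p = 0.00744). Acadl, the long-chain acyl-CoA dehydrogenase, rose 1.20-fold (0.27 ± 0.050, adjusted p = 0.0242). Fos, an immediate early transcription factor, had the largest rise, 2.55-fold (1.35 ± 0.24, adjusted p = 0.022). The insulin receptor substrate Irs2 rose 1.32-fold (0.40 ± 0.083, adjusted p = 0.0289).

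Of the 18 measured genes of fatty acid synthesis, 6 fell and 12 did not pass the test, and 7 fell adjusted over the list alone. Camera gave fatty acid synthesis an adjusted p = 0.00125, and adjusted p = 0.46 with an estimated correlation. Those that fell included Fasn (-2.15 ± 0.28), the elongase Elovl6 (-1.22 ± 0.20), the ATP citrate lyase Acly (-1.10 ± 0.20) and the acetyl-CoA carboxylase Acaca (-0.91 ± 0.17). The mean of the 13 measured adipocyte markers was 9.61 ± 0.39 on chow and 9.02 ± 0.16 at 5 days (log2, SD, n = 4). That of 3 brown adipocyte markers (Ucp1, Cidea and Otop1) was 8.13 ± 0.82 and 6.95 ± 0.10. Among the adipocyte markers, 3 fell and 10 did not pass the test, and 9 fell adjusted over the list alone. Camera gave adipocyte markers an adjusted p = 4.85e-06, and adjusted p = 0.457 with an estimated correlation. Resistin, or Retn (-0.97 ± 0.21), and the lipid droplet protein Cidec (-1.33 ± 0.34) were among those that fell. In the list of brown adipocyte markers, 1 fell and 9 did not pass the test, and 4 fell adjusted over the list alone. Camera gave brown adipocyte markers an adjusted p = 0.0346, and adjusted p = 0.46 with an estimated correlation. Cidea (-1.65 ± 0.44) fell, while the uncoupling protein Ucp1 was at -1.47 ± 0.42 (adjusted p = 0.0621). The list of triglyceride storage and lipolysis was not past its test (adjusted p = 0.202), though 4 of its 21 members fell, among them Mogat1 (-0.32 ± 0.069), G0s2 (-0.47 ± 0.12) and Cidea.

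**Figure D1:**
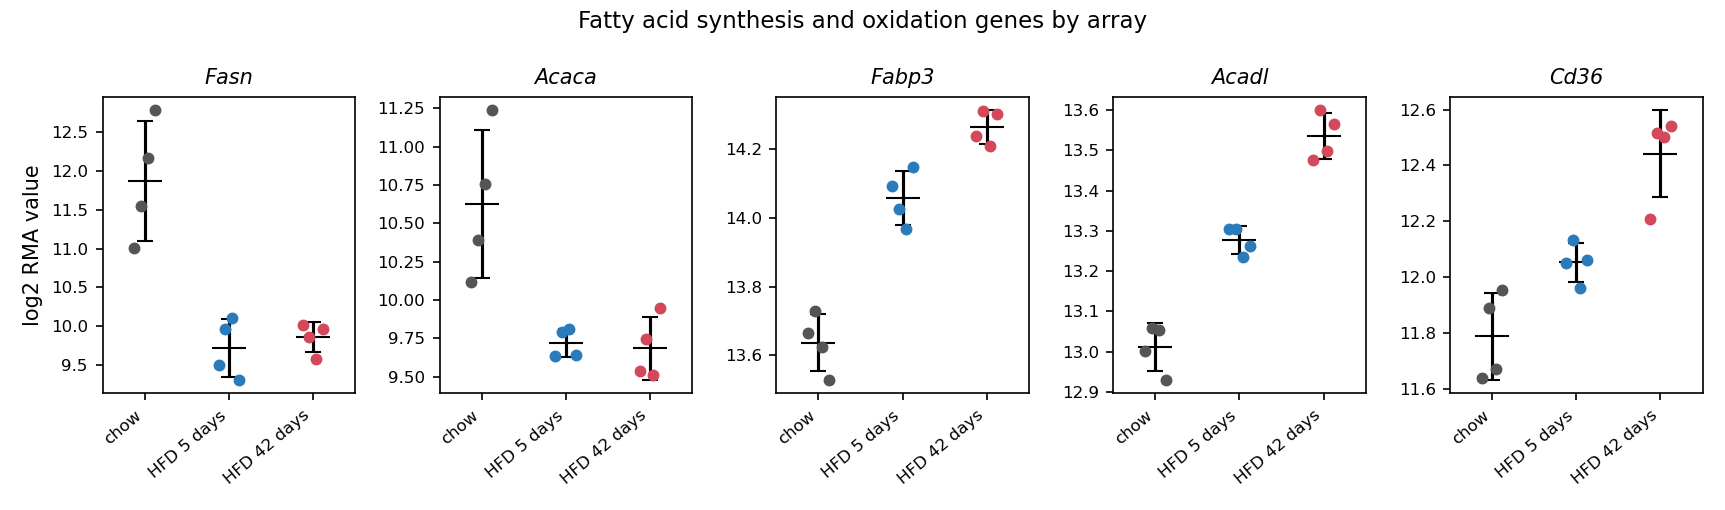
Log2 RMA signal (vertical axis) of Fasn, Acaca, Fabp3, Acadl and Cd36 in the 3 groups (horizontal axis). Points are arrays (4 per group), the bar is the mean and the error bar the SD. Fasn averaged 11.88 on chow, 9.72 at 5 days and 9.86 at 42 days.

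Fatty acid oxidation had 21 measured members, of which 4 rose and 17 did not pass the test, and 13 rose adjusted over the list alone. Camera gave fatty acid oxidation an adjusted p = 3.88e-09, and adjusted p = 0.457 with an estimated correlation. Beside Fabp3 and Acadl, Etfdh (0.29 ± 0.058), which passes electrons to ubiquinone, and Hadha (0.20 ± 0.052) of the trifunctional protein rose. The TCA cycle and pyruvate dehydrogenase had 25 measured members, all 25 at higher values, of which 2 rose and 23 did not pass the test, and 3 rose adjusted over the list alone. Camera gave the TCA cycle list an adjusted p = 1.34e-05, and adjusted p = 0.457 with an estimated correlation. Dlat (0.28 ± 0.046) and Pdhx (0.33 ± 0.065) rose, and Dld (0.20 ± 0.057, adjusted p = 0.0617) was not past the test. Within oxidative phosphorylation, with 73 measured genes, 1 rose and 72 did not pass the test, and 1 rose adjusted over the list alone. Camera gave oxidative phosphorylation an adjusted p = 0.00111, and adjusted p = 0.69 with an estimated correlation. The member that rose was Ndufs1 (0.24 ± 0.052), a subunit of complex I. In mitochondrial biogenesis and dynamics, 21 of 23 measured members had higher values, 7 of them at an unadjusted p under 0.05 by limma, and 0 passed over all genes or adjusted over the list alone. Camera gave mitochondrial biogenesis and dynamics an adjusted p = 0.000114, and adjusted p = 0.457 with an estimated correlation. The fusion protein Opa1 (0.15 ± 0.046, adjusted p = 0.0767) is an example. Of 17 slow fibre genes, 0 passed limma's test over all genes, 8 were higher at an unadjusted p under 0.05, and 3 rose adjusted over the list alone. Camera gave slow fibre genes an adjusted p = 3.35e-05, and adjusted p = 0.457 with an estimated correlation. Examples are Tnnc1 (0.37 ± 0.11, adjusted p = 0.0675) and Lmcd1 (0.34 ± 0.11, adjusted p = 0.0779). Insulin signalling had 29 measured genes, of which 1 rose and 28 did not pass the test, and 1 rose adjusted over the list alone. Camera gave insulin signalling an adjusted p = 0.00287, and adjusted p = 0.46 with an estimated correlation. Irs2 was the gene that rose, and Pik3ca (0.19 ± 0.060, adjusted p = 0.0779) was not past the test. In 10 bins of all genes by mean signal, the bright bins 8, 9 and 10 had median changes of 0.055, 0.080 and 0.051. List medians were of similar size for the TCA cycle (0.081), oxidative phosphorylation (0.042), mitochondrial biogenesis and dynamics (0.097) and insulin signalling (0.075). Those of fatty acid oxidation (0.148) and slow fibre genes (0.237) were larger.

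Immediate early genes had 23 measured members, of which 8 rose and 15 did not pass the test, and 14 rose adjusted over the list alone. Camera gave immediate early genes an adjusted p = 3.81e-09, and adjusted p = 0.457 with an estimated correlation. Btg2 (0.52 ± 0.092), Ier5 (0.50 ± 0.090) and the phosphatase Dusp1 (0.59 ± 0.11) rose, as did Fos. Extracellular matrix genes had 30 measured members, of which 6 rose and 24 did not pass the test, and 19 rose adjusted over the list alone. Camera gave extracellular matrix an adjusted p = 5.83e-10, and adjusted p = 0.457 with an estimated correlation. The lysyl oxidase-like enzyme Loxl1 (0.28 ± 0.066), the connective tissue growth factor Ccn2 (0.50 ± 0.12) and the collagen chain Col5a2 (0.40 ± 0.10) rose. Endothelial markers had 19 measured members, of which 2 rose and 17 did not pass the test, and 7 rose adjusted over the list alone. Camera gave endothelial markers an adjusted p = 3.35e-05, and adjusted p = 0.457 with an estimated correlation. The von Willebrand factor Vwf (0.33 ± 0.074) and the tight junction protein Cldn5 (0.37 ± 0.086) rose. In ER stress and the integrated stress response, of 27 measured genes 2 rose and 25 did not pass the test, and 2 rose adjusted over the list alone. Camera gave the ER stress list an adjusted p = 0.0234, and adjusted p = 0.465 with an estimated correlation. Xbp1 (0.30 ± 0.074) rose and Atf3 (0.93 ± 0.30, adjusted p = 0.0854) did not pass. Of the 25 measured interferon response and antigen processing genes, 1 fell and 24 did not pass the test, and 3 fell adjusted over the list alone. Camera gave the interferon list an adjusted p = 0.0243, and adjusted p = 0.69 with an estimated correlation. The gene that fell was Oas1a (-0.28 ± 0.053). Among lymphocyte markers, 15 of 18 members were lower, 7 of them at an unadjusted p under 0.05 by limma, 0 passed over all genes and 5 fell adjusted over the list alone. Camera gave lymphocyte markers an adjusted p = 0.00287, and adjusted p = 0.457 with an estimated correlation. Cd3e was at -0.18 ± 0.055 (adjusted p = 0.0687).

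The 8 largest rises past the test were Fos (1.35 ± 0.24), Otud1 (0.98 ± 0.24), Tmem252 (0.68 ± 0.091), Bhmt2 (0.67 ± 0.16), Tcp11x2 (0.65 ± 0.11), Adamts1 (0.61 ± 0.11), Saa2 (0.60 ± 0.14) and Apold1 (0.59 ± 0.13). Bhmt2 (5.33 on chow, 6.00 at 5 days), Tcp11x2 (6.26 and 6.91) and Saa2 (6.57 and 7.17) were dim. The lower quartile of the arrays averaged 6.51 on chow and 6.45 at 5 days. The other probe sets of Bhmt2 (-0.027) and Tcp11x2 (-0.0018) did not rise. The 8 largest falls were Fasn (-2.15 ± 0.28), Cidea (-1.65 ± 0.44), Tkt (-1.56 ± 0.30), Slc25a1 (-1.38 ± 0.22), H2-Q10 (-1.35 ± 0.31), Cidec (-1.33 ± 0.34), Cdo1 (-1.31 ± 0.26) and Elovl6 (-1.22 ± 0.20). Tkt is the transketolase of the pentose phosphate pathway and Slc25a1 the mitochondrial citrate carrier. Of the 16 measured genes of the fixed metabolic panel, Fasn and Scd1 (-1.14 ± 0.29) fell and Irs2 rose. The other 13 (Pdk4, Ucp3, Angptl4, Cd36, Plin2, Srebf1, Slc2a4, Hk2, Irs1, Insr, Ppargc1a, Adipoq and Lep) were not past the test, with log2 fold changes from -1.05 for Adipoq to 0.26 for Cd36 and adjusted p of 0.0815 to 0.98.

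Across 18193 genes, 692 passed limma's test at an adjusted p under 0.05, of which 291 rose and 401 fell. Of these, 33 changed over 1.5-fold and 14 over 2-fold, and the median size of change was 0.28 on the log2 scale. The groups did not overlap in 2140 of all 18193 genes, or 11.8%, where chance gives 2.86%, and in 624 of the genes past the test. In 10 bins of equal size by mean signal, the median change ran from -0.083 in bin 3 to 0.080 in bin 9, with brighter genes higher. The count was 6 without 5-day replicate 2, 132 without 5-day replicate 4, 139, 223 and 310 without chow replicates 1, 3 and 4, and 332, 323 and 406 without 42-day replicates 2, 3 and 4. It was 7 in a fit of the 8 arrays alone, 159 with array weights, 208 after quantile normalization, 1343 with arrays centred on their median (84.6% rose) and 33 with the adipocyte marker mean as a covariate. Of 41 named genes past the test, 3 (Fabp3, Fasn and Tmem252) passed without each array in turn, 18 did not pass after cyclic loess and 39 did not with the adipocyte covariate. With loess the 18 log2 fold changes stayed within 1.5 times, as did 27 of the 39 with the covariate. The other 12 shrank further: Acaca (-0.40), Acly (-0.73), Cdo1 (-0.50), Cidea (-0.38), Cidec (-0.14), Elovl6 (-0.75), G0s2 (-0.25), H2-Q10 (-0.57), Retn (-0.30), Scd1 (-0.26), Slc25a1 (-0.77) and Tkt (-0.71). Cidec and Retn are part of the marker mean used as the covariate, so their shrinkage is partly built in. The groups overlapped in Cidea, Cldn5, Col5a2 and Otud1. With the mean of a gene's probe sets, 7 named calls ended, and the log2 fold change moved over 1.5 times in 5 of them: Bhmt2 (0.32), Etfdh (0.10), Fabp3 (0.17), Loxl1 (0.11) and Xbp1 (0.11). It moved as far in 5 that still passed: Acaca (-0.52), Acly (-0.46), Ier5 (0.32), Tcp11x2 (0.32) and Tkt (-1.02). The most variable probe set put Btg2 at 0.84.

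Of 36 gene lists, 15 were past camera's test, 10 up and 5 down. With an estimated correlation 0 were, 2 had an unadjusted p under 0.05, and fry called 3. The other 21 lists had adjusted p of 0.0784 to 0.974. Median, mean and test differed in sign, the test pointing up, for sphingolipid synthesis and turnover (0.0038 and -0.018), glycolysis and glycogen (-0.010 and -0.0027), fast fibre (-0.0043 and -0.0040), myogenic and denervation genes (-0.010 and 0.013), heat shock (0.015 and -0.0025) and secreted muscle factors (0.0091 and -0.0088), given as median and mean. Cyclic loess ended the calls of insulin signalling (adjusted p = 0.341), oxidative phosphorylation (0.628), ER stress (0.232), brown adipocyte (0.217) and lymphocyte markers (0.0569). The adipocyte covariate ended those of fatty acid synthesis (0.276), oxidative phosphorylation (0.197), slow fibre (0.194), brown adipocyte (0.524), interferon response (0.153, direction turned) and adipocyte markers (0.934, direction turned). That covariate is the mean of the adipocyte markers themselves, so the loss of their own call was fixed in advance. Single arrays ended the calls of oxidative phosphorylation (0.0686 without chow replicate 4), ER stress (0.0624 without 5-day replicate 2) and interferon response (0.619 without chow replicate 4, direction turned, and also without 5-day replicate 3). Brown adipocyte markers lost theirs (up to 0.0756, without chow replicates 2, 3 or 4 or 5-day replicates 1 or 3). Quantile normalization also ended those of insulin signalling (0.312), ER stress (0.183), brown adipocyte (0.207) and lymphocyte markers (0.0593). Leaving out dim genes ended those of insulin signalling (0.0562) and ER stress (0.0886). The 3-prime to 5-prime covariate ended those of ER stress (0.0782), interferon response (0.19) and brown adipocyte markers (0.0673).

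The second comparison asked which transcripts differed after 42 days on the high-fat diet, against the same chow arrays. Fasn fell from 11.88 ± 0.77 to 9.86 ± 0.20 (log2 signal, SD, n = 4), a change of -2.02 ± 0.28 or 4.05-fold lower (limma, adjusted p = 0.00328). Oxidation genes rose: Fabp3 was 1.55-fold higher (0.63 ± 0.057, adjusted p = 0.000264), Acadl 1.44-fold higher (0.52 ± 0.050, adjusted p = 0.000264) and the fatty acid transporter Cd36 1.57-fold higher (0.65 ± 0.084, adjusted p = 0.00202). Alb, the serum albumin made in liver, had the largest rise, from 9.68 ± 0.39 on chow to 11.87 ± 0.59 (2.19 ± 0.39, 4.56-fold higher, adjusted p = 0.00893). Fmod, a small proteoglycan abundant in tendon, rose 1.98-fold (0.98 ± 0.16, adjusted p = 0.00692).

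Of the 18 measured genes of fatty acid synthesis, 9 fell and 9 did not pass the test, and 1 rose and 11 fell adjusted over the list alone. Camera gave fatty acid synthesis an adjusted p = 1.66e-05, and adjusted p = 0.468 with an estimated correlation. Acly (-1.27 ± 0.20), Acaca (-0.94 ± 0.17) and Elovl6 (-1.08 ± 0.20) fell beside Fasn. The adipocyte marker mean was 9.19 ± 0.32 at 42 days against 9.61 ± 0.39 on chow, and the mean of Ucp1, Cidea and Otop1 7.30 ± 0.53 against 8.13 ± 0.82 (log2, SD, n = 4). Of all 10 measured brown adipocyte markers 7 were higher, with a median of 0.069 and a mean of -0.18, and the list was not past its test (adjusted p = 0.464). Ucp1 (-1.05) and Cidea (-1.27) were among the 3 lower ones, neither past the test. Among the 13 adipocyte markers, 12 were lower, 6 of them at an unadjusted p under 0.05 by limma, 0 passed over all genes and 2 fell adjusted over the list alone. Camera gave adipocyte markers an adjusted p = 0.00619, and adjusted p = 0.8 with an estimated correlation. Retn (-0.69 ± 0.21, adjusted p = 0.0703) and Cidec (-0.98 ± 0.34, adjusted p = 0.108) are examples. Triglyceride storage and lipolysis had 21 measured genes, of which 3 fell and 18 did not pass the test, and 1 rose and 9 fell adjusted over the list alone. Camera gave triglyceride storage and lipolysis an adjusted p = 0.004, and adjusted p = 0.773 with an estimated correlation. Mogat1 (-0.28 ± 0.069) and the lipase inhibitor G0s2 (-0.46 ± 0.12) fell.

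In fatty acid oxidation, all 21 measured members had higher values: 11 rose and 10 did not pass the test, and 17 rose adjusted over the list alone. Camera gave fatty acid oxidation an adjusted p = 2.59e-18, and adjusted p = 0.283 with an estimated correlation. Etfdh (0.45 ± 0.058) rose, as did Fabp3, Acadl and Cd36. The TCA cycle and pyruvate dehydrogenase had 25 measured genes, of which 4 rose and 21 did not pass the test, and 5 rose adjusted over the list alone. Camera gave the TCA cycle list an adjusted p = 1.66e-05, and adjusted p = 0.496 with an estimated correlation. Dlat (0.30 ± 0.046), Pdhx (0.30 ± 0.065) and Dld (0.30 ± 0.057) of the pyruvate dehydrogenase complex rose. All 17 measured slow fibre genes had higher values, of which 1 rose and 16 did not pass the test, and 5 rose adjusted over the list alone. Camera gave slow fibre genes an adjusted p = 4.7e-07, and adjusted p = 0.468 with an estimated correlation. The gene that rose was Lmcd1 (0.48 ± 0.11). The mean 3-prime to 5-prime difference of 4 control transcripts, a sign of RNA integrity, was 0.89 ± 0.078 at 42 days and 1.07 ± 0.063 on chow (log2, SD, n = 4). For the control Pcx alone it was 1.235 ± 0.17 and 1.925 ± 0.28, without overlap (highest 1.49 against lowest 1.63). The groups did not overlap for Actb and Gapdh either, both lower at 42 days. Tfrc was not lower (2.08 to 2.36 against 1.86 to 2.28), and the covariate used the mean of all 4. Extracellular matrix genes had 30 measured members, of which 9 rose and 21 did not pass the test, and 15 rose adjusted over the list alone. Camera gave extracellular matrix an adjusted p = 7.34e-11, and adjusted p = 0.542 with an estimated correlation. Fmod, the collagen crosslinking enzymes Lox (0.52 ± 0.10) and Loxl1 (0.29 ± 0.066), and the proteoglycan Lum (0.70 ± 0.16) rose. In a list of tendon transcripts written afterwards, all 8 whose values had not been seen were also higher, and 4 of them rose. The tissue from which the matrix transcripts came was not tested. Bone and cartilage markers had 12 measured members, of which 3 rose and 9 did not pass the test, and 3 rose adjusted over the list alone. Camera gave bone and cartilage markers an adjusted p = 0.004, and adjusted p = 0.468 with an estimated correlation. The cartilage matrix proteins Comp (0.55 ± 0.10), Cilp2 (0.28 ± 0.061) and Chad (0.61 ± 0.17) rose. In lists that were not past their tests, Xbp1 (0.33 ± 0.074) and Ndufs1 (0.19 ± 0.052) rose, and Eif4ebp1 (-0.35 ± 0.073), Mmut (-0.24 ± 0.059), Pfkfb3 (-0.69 ± 0.17) and Rictor (-0.28 ± 0.065) fell.

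The 8 largest rises were transcripts known as liver products: Alb (2.19 ± 0.39), Serpina1b (1.93 ± 0.42), Serpina1c (1.86 ± 0.36), Fabp1 (1.85 ± 0.36), Apoa1 (1.81 ± 0.42), Mug1 (1.44 ± 0.37), Bhmt (1.38 ± 0.27) and Fgg (1.28 ± 0.31). The 8 largest falls were Fasn (-2.02 ± 0.28), Tkt (-1.71 ± 0.30), Acly (-1.27 ± 0.20), Slc25a1 (-1.26 ± 0.22), Malat1 (-1.24 ± 0.22), Scd1 (-1.15 ± 0.29), Elovl6 (-1.08 ± 0.20) and Rgs2 (-1.06 ± 0.29). Malat1 is a nuclear long noncoding RNA. Of the 16 panel genes, Fasn and Scd1 fell and Cd36 rose. The other 13 (Pdk4, Ucp3, Angptl4, Plin2, Srebf1, Slc2a4, Hk2, Irs1, Irs2, Insr, Ppargc1a, Adipoq and Lep) did not pass, with log2 fold changes from -0.84 for Adipoq to 0.095 for Lep and adjusted p of 0.0973 to 0.956. With their most variable probe sets Slc2a4 was at 0.52 (adjusted p = 0.00202) and Ucp3 at 0.47 (adjusted p = 0.0191), the other direction from the probe sets used.

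**Figure D2:**
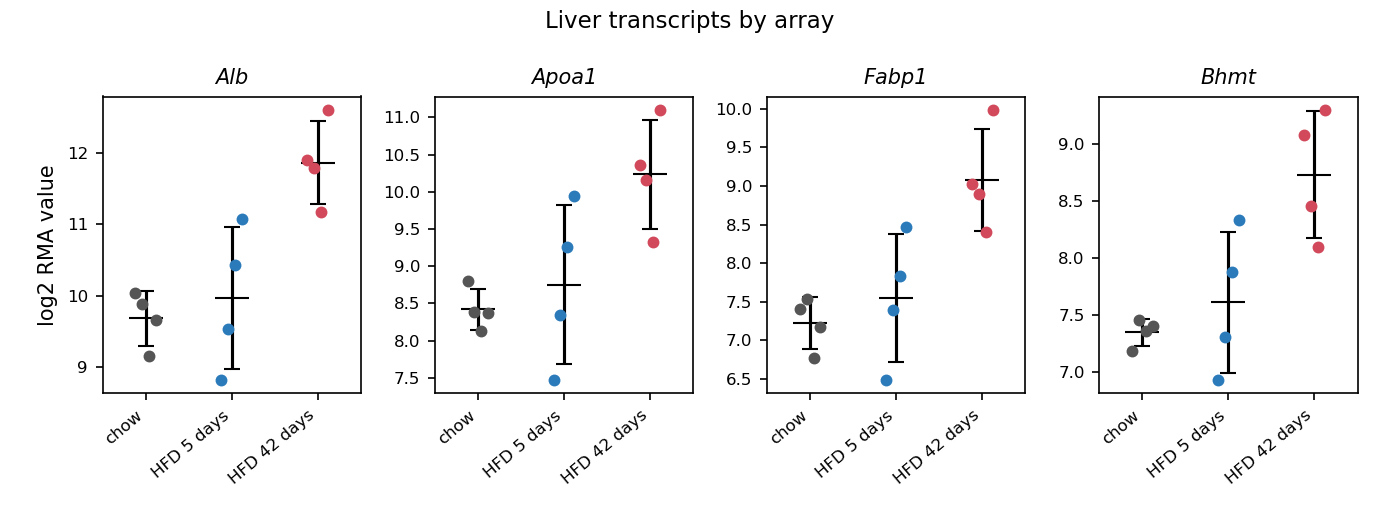
Log2 RMA signal (vertical axis) of the liver transcripts Alb, Apoa1, Fabp1 and Bhmt in the 3 groups (horizontal axis). Points are arrays (4 per group), the bar is the mean and the error bar the SD. Alb averaged 9.68 on chow, 9.97 at 5 days and 11.87 at 42 days.

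In all, 1011 genes passed limma's test: 386 rose and 625 fell, 74 changed over 1.5-fold (51 up, 23 down) and 21 over 2-fold, with a median size of 0.30 on the log2 scale. Groups without overlap were found in 13.9% of all genes (chance share 2.86%) and in 936 of those past the test. The median change by signal bin ran from 0.023 in bin 1 to -0.051 in bin 8. The count was 228 and 598 without chow replicates 3 and 4, and 400, 388, 572 and 298 without 42-day replicates 1, 2, 3 and 4. It was 10 with the 3-prime to 5-prime difference as a covariate and 167 with the adipocyte marker mean; the share that rose, 38.2%, was 58% with the mean of a gene's probe sets. Of 51 named genes past the test, 19 passed without each array in turn, Fabp3, Acadl and Fasn among them, and 34 did not with the adipocyte covariate. Of these 34, 28 kept their log2 fold changes within 1.5 times and 6 did not: Cdo1 (-0.37), Eif4ebp1 (-0.23), G0s2 (-0.30), Pfkfb3 (-0.42), Rgs2 (-0.48) and Scd1 (-0.52). Acaca (-0.58), Slc25a1 (-0.83) and Tkt (-1.10) shrank as far and still passed. The 3-prime to 5-prime covariate ended 49 of the named calls, 33 of them with log2 fold changes within 1.5 times. Those beyond were Acaca (-0.63), Ccn2 (0.12), Cdo1 (-0.26), Chad (0.30), Cilp2 (0.18), Elovl6 (-0.63), Lmcd1 (0.25), Malat1 (-0.81), Ndufs1 (0.10), Pfkfb3 (-0.21), Rgs2 (-0.23), Rictor (-0.42), Scd1 (-0.76), Slc25a1 (-0.75), Tkt (-1.05) and Zbed6 (-0.25). The groups overlapped in Cdo1, G0s2 and Rgs2. The mean of probe sets ended 12 named calls and moved 9 of these log2 fold changes over 1.5 times: Col5a2 (0.20), Crebbp (-0.077), Dld (0.16), Loxl1 (0.16), Mmut (-0.080), Pfkfb3 (-0.30), Rgs2 (-0.57), Rictor (-0.055) and Xbp1 (0.0058). A further 13 moved as far and still passed: Acaca (-0.41), Acadl (0.32), Acly (-0.41), Cd36 (0.39), Dlat (0.18), Etfdh (0.24), Fabp3 (0.33), Fmod (0.64), Gmps (-0.18), Malat1 (-0.78), Mup3 (0.62), Tcp11x2 (0.25) and Tkt (-0.999). The most variable probe set ended the call of Scd1 and put Lox at 0.80.

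Of 36 lists, 8 were past camera's test, 5 up and 3 down. With an estimated correlation 0 were, 2 had an unadjusted p under 0.05, and fry called 5. The other 28 lists had adjusted p of 0.09 to 0.99. Fast fibre (-0.0010 and 0.0028), heat shock (-0.0083 and -0.049), brown adipocyte (0.069 and -0.18), macrophage (-0.015 and 0.058) and neutrophil (-0.021 and 0.0042) lists had a median and mean (given in that order) of which 1 or both were negative while the test pointed up. The 3-prime to 5-prime covariate ended the calls of triglyceride storage (0.778), the TCA cycle (0.176), slow fibre (0.0629) and adipocyte markers (0.607, direction turned), given as adjusted p. The adipocyte covariate ended those of triglyceride storage (0.606) and adipocyte markers (0.861, direction turned), the latter by construction, since the covariate is the mean of these markers. The adipocyte call was also lost without chow replicate 4 or 42-day replicate 1 (up to 0.236), and both calls without the 40% dimmest genes (0.0781 and 0.0611).

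The third comparison set 42 days against 5 days on the diet, where the diet was the same and the time on it differed. Both groups started the diet at 6 weeks, so the age at sampling differed along with the time on the diet. Irs2 was lower at 42 days, 8.80 ± 0.11 against 9.42 ± 0.18 (log2 signal, SD, n = 4), a change of -0.62 ± 0.083, or 1.54-fold (limma, adjusted p = 0.0114). Fos fell 2.43-fold (-1.28 ± 0.24, adjusted p = 0.0172) and Ppargc1a, the coactivator of mitochondrial biogenesis, 1.35-fold (-0.44 ± 0.10, adjusted p = 0.0232). Cd36 rose 1.31-fold (0.39 ± 0.084, adjusted p = 0.0222), and Alb rose 3.75-fold (1.91 ± 0.39, adjusted p = 0.0182).

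Insulin signalling had 29 measured genes, of which 7 fell and 22 did not pass the test, and 8 fell adjusted over the list alone. Camera gave insulin signalling an adjusted p = 0.000548, and adjusted p = 0.612 with an estimated correlation. Beside Irs2, Pdpk1 (-0.27 ± 0.066), Rictor (-0.26 ± 0.065), Pik3ca (-0.23 ± 0.060) and the insulin receptor Insr (-0.24 ± 0.063) fell. Mitochondrial biogenesis and dynamics had 23 measured genes, of which 7 fell and 16 did not pass the test, and 8 fell adjusted over the list alone. Camera gave mitochondrial biogenesis and dynamics an adjusted p = 0.000203, and adjusted p = 0.612 with an estimated correlation. Opa1 (-0.22 ± 0.046), Ppard (-0.27 ± 0.059) and Ppargc1a fell. With the mean of their probe sets, Opa1 was at 0.095 and Rictor at 0.012, so the direction turned, and Opa1 was at 0.37 with its most variable probe set. The mean of probe sets left Insr at -0.027 (adjusted p = 0.735), Ppard at -0.047, Ier5 at -0.090 and Hspa5 at -0.062, none past the test. The most variable probe set left Insr at -0.016, Ier5 at -0.0015 and Hspa5 at -0.10, also not past it. The 3-prime to 5-prime difference was 0.89 ± 0.078 at 42 days and 1.02 ± 0.075 at 5 days (log2, SD, n = 4), and genes in signal bin 9 had a median change of -0.12. Fatty acid oxidation had 21 measured genes, of which 5 rose and 16 did not pass the test, and 8 rose adjusted over the list alone. Camera gave fatty acid oxidation an adjusted p = 0.00139, and adjusted p = 0.66 with an estimated correlation. Acadl (0.26 ± 0.050), the transport protein Slc27a1 (0.24 ± 0.062) and Fabp3 (0.21 ± 0.057) rose, as did Cd36. Among 23 immediate early genes, 7 fell and 16 did not pass the test, and 11 fell adjusted over the list alone. Camera gave immediate early genes an adjusted p = 0.000406, and adjusted p = 0.612 with an estimated correlation. Btg2 (-0.58 ± 0.092), Fosl2 (-0.48 ± 0.089) and Ier5 (-0.38 ± 0.090) fell beside Fos. The circadian clock list had 18 measured genes, of which 4 fell and 14 did not pass the test, and 6 fell adjusted over the list alone. Camera gave the circadian clock list an adjusted p = 0.00258, and adjusted p = 0.612 with an estimated correlation. The clock repressors Per1 (-0.30 ± 0.055) and Cry2 (-0.25 ± 0.056) fell. Branched-chain amino acid catabolism had 19 measured genes, of which 1 fell and 18 did not pass the test, and 1 fell adjusted over the list alone. Camera gave branched-chain amino acid catabolism an adjusted p = 0.00258, and adjusted p = 0.66 with an estimated correlation. The mutase Mmut (-0.31 ± 0.059) fell. Among 23 atrophy and glucocorticoid-induced genes, 1 fell and 22 did not pass the test, and 1 fell adjusted over the list alone. Camera gave the atrophy list an adjusted p = 0.0129, and adjusted p = 0.66 with an estimated correlation. The translation repressor Eif4ebp1 (-0.33 ± 0.073) fell. ER stress and the integrated stress response had 27 measured genes, of which 3 fell and 24 did not pass the test, and 6 fell adjusted over the list alone. Camera gave the ER stress list an adjusted p = 0.0487, and adjusted p = 0.66 with an estimated correlation. The chaperone Hspa5 (-0.25 ± 0.064) and the stress factor Atf3 (-1.05 ± 0.30) fell. Among all genes, the bright bins 8, 9 and 10 had median changes of -0.11, -0.12 and -0.083. List medians were of similar size for insulin signalling (-0.123), mitochondrial biogenesis and dynamics (-0.12), branched-chain amino acid catabolism (-0.115), atrophy genes (-0.123), circadian clock (-0.125) and ER stress (-0.105). That of immediate early genes (-0.253) was larger, and that of fatty acid oxidation (0.103) had the other sign.

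**Figure D3:**
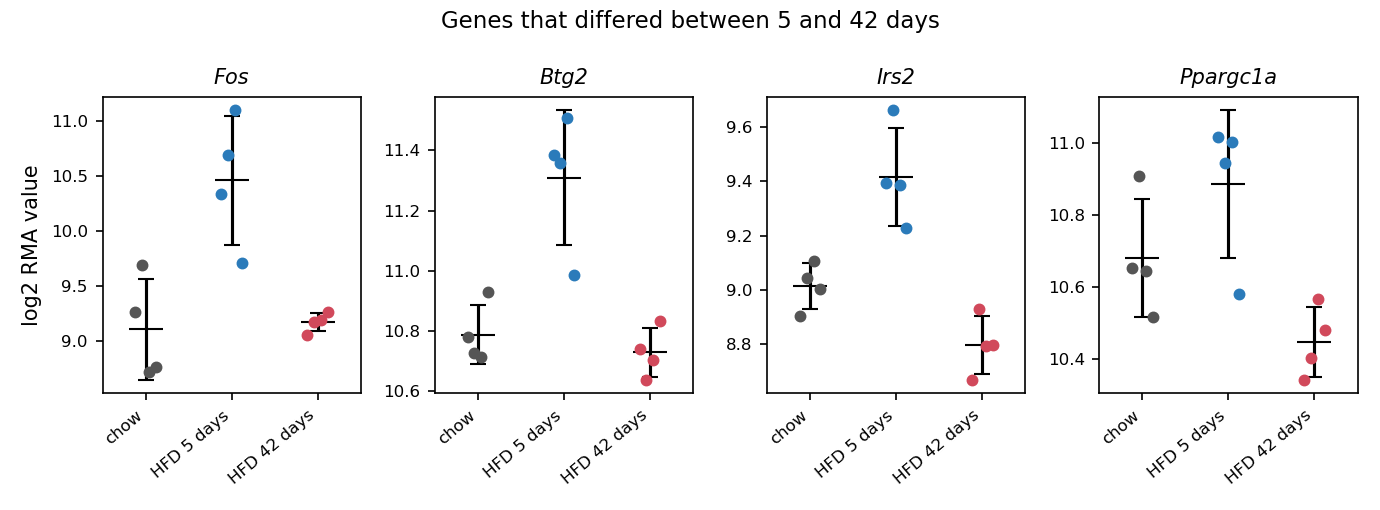
Log2 RMA signal (vertical axis) of Fos, Btg2, Irs2 and Ppargc1a in the 3 groups (horizontal axis). Points are arrays (4 per group), the bar is the mean and the error bar the SD. Fos averaged 9.11 on chow, 10.46 at 5 days and 9.18 at 42 days.

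Of 30 measured inflammatory cytokine and NF-kB genes, 1 rose, 1 fell and 28 did not pass the test, and 7 rose and 2 fell adjusted over the list alone. Camera gave the inflammatory list an adjusted p = 0.0243, and adjusted p = 0.645 with an estimated correlation. The acute phase gene Saa3 (0.22 ± 0.064) rose. Lymphocyte markers had 18 measured genes, 17 of them at higher values, of which 1 rose and 17 did not pass the test, and 1 rose adjusted over the list alone. Camera gave lymphocyte markers an adjusted p = 0.00124, and adjusted p = 0.612 with an estimated correlation. The T cell receptor complex chain Cd3e (0.23 ± 0.055) rose. Brown adipocyte markers had 10 measured genes, all at higher values, of which 2 rose and 8 did not pass the test, and 2 rose adjusted over the list alone. Camera gave brown adipocyte markers an adjusted p = 0.0078, and adjusted p = 0.612 with an estimated correlation. The elongase Elovl3 (0.27 ± 0.065) rose, as did Slc27a2 (0.41 ± 0.11), a very-long-chain acyl-CoA synthetase known from liver and kidney. The mean of Ucp1, Cidea and Otop1 was 7.30 ± 0.53 at 42 days and 6.95 ± 0.10 at 5 days (log2, SD, n = 4). Endothelial markers had 19 measured genes, of which 1 fell and 18 did not pass the test, and 1 fell adjusted over the list alone. Camera gave endothelial markers an adjusted p = 0.0391, and adjusted p = 0.66 with an estimated correlation. Vwf (-0.33 ± 0.074) fell. Bone and cartilage markers had 12 measured genes, of which 1 rose, 1 fell and 10 did not pass the test, and 2 rose and 1 fell adjusted over the list alone. Camera gave bone and cartilage markers an adjusted p = 0.0487, and adjusted p = 0.612 with an estimated correlation. Comp (0.34 ± 0.10) rose and the alkaline phosphatase Alpl (-0.18 ± 0.050) fell, while Chad (0.44 ± 0.17, adjusted p = 0.0942) and Cilp2 (0.15 ± 0.061, adjusted p = 0.108) were not past the test.

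The 8 largest rises were Alb (1.91 ± 0.39), Serpina1b (1.58 ± 0.42), Fabp1 (1.53 ± 0.36), Apoa1 (1.48 ± 0.42), Serpina1c (1.37 ± 0.36), Mug1 (1.29 ± 0.37), Bhmt (1.12 ± 0.27) and Mup3 (1.01 ± 0.25), all known as liver products. The 8 largest falls were Fos (-1.28 ± 0.24), Atf3 (-1.05 ± 0.30), Malat1 (-1.04 ± 0.22), Irs2 (-0.62 ± 0.083), Btg2 (-0.58 ± 0.092), Crebbp (-0.57 ± 0.085), Zbed6 (-0.56 ± 0.11) and Gmps (-0.56 ± 0.070). Of the panel, Irs2, Hk2 (-0.22 ± 0.047), Insr and Ppargc1a fell and Cd36 rose. The other 11 (Pdk4, Ucp3, Angptl4, Plin2, Scd1, Fasn, Srebf1, Slc2a4, Irs1, Adipoq and Lep) did not pass, with log2 fold changes from -0.16 for Ucp3 to 0.21 for Adipoq and adjusted p of 0.273 to 0.983.

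**Figure D4:**
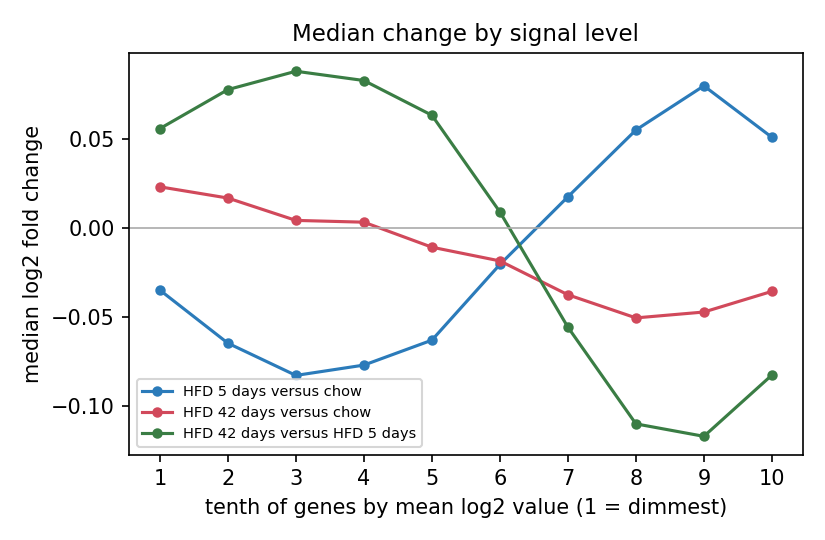
Median log2 fold change (vertical axis) of genes in 10 bins of equal size by mean signal, from 1 (dimmest) to 10 (horizontal axis), 1 line per comparison. In the comparison of 42 with 5 days the line falls from 0.088 in bin 3 to -0.12 in bin 9.

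Between the times, 1550 genes passed limma's test: 501 rose and 1049 fell, 34 changed over 1.5-fold and 11 over 2-fold. The groups were apart in 20.4% of all genes (chance share 2.86%) and in 1397 of those past the test. By signal bin, the median change ran from 0.088 in bin 3 to -0.12 in bin 9, and in bin 9 300 genes fell and 14 rose. Without 42-day replicate 1 limma called 0 genes (4107 at an unadjusted p under 0.05), and without 5-day replicates 2 and 3 or 42-day replicates 2, 3 and 4 it called 16, 395, 250, 964 and 607. It called 363 after cyclic loess, 371 after quantile normalization, 3474 with centred arrays and, with the 3-prime to 5-prime covariate, 0 (3955 unadjusted). Of 45 named genes past the test by limma, each failed it without 1 array or more and 27 after cyclic loess. After loess 20 of these 27 kept their log2 fold changes within 1.5 times, and 7 did not: Cry2 (-0.15), Hspa5 (-0.16), Insr (-0.14), Opa1 (-0.13), Pdpk1 (-0.17), Per1 (-0.20) and Pik3ca (-0.13). With the 3-prime to 5-prime covariate, Fmod (0.41), Saa3 (0.14) and Zbed6 (-0.35) moved as far. The groups overlapped in Apoa1, Atf3, Bhmt, Comp, Fabp1, Fmod, Ier5, Mug1, Mup3, Serpina1b, Serpina1c and Slc27a2. The mean of probe sets ended 29 of the 45 calls. Beside Opa1, Rictor, Insr, Ier5, Ppard and Hspa5, those that also moved over 1.5 times were Acadl (0.13), Cd36 (0.20), Eif4ebp1 (-0.21), Fmod (0.35), Fosl2 (-0.19), Malat1 (-0.53), Mmut (-0.13), Mup3 (0.45) and Ppargc1a (-0.26). Crebbp (-0.31), Gmps (-0.28) and Zbed6 (-0.34) moved as far and still passed. The most variable probe set ended 7 calls, Slc27a1 (0.15) among them, and put Btg2 at -0.98.

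Of 36 lists, 13 were past camera's test, 5 up and 8 down. With an estimated correlation 0 were, 2 had an unadjusted p under 0.05, and fry called 4. The other 23 had adjusted p of 0.105 to 0.988. Median, mean and test differed in sign for sphingolipid synthesis (-0.024 and 0.00067, test down), the TCA cycle (0.0023 and 0.0011, down), interferon response (-0.0038 and -0.0034, up) and extracellular matrix (-0.018 and 0.0061, down). Cyclic loess ended the calls of insulin signalling (0.138), branched-chain amino acid catabolism (0.351), atrophy genes (0.351), ER stress (0.351), inflammatory genes (0.0611), and brown adipocyte markers (0.0611). It also ended those of endothelial (0.19) and bone and cartilage markers (0.0797), given as adjusted p. Leaving out dim genes ended that of the circadian clock (0.0664). Single arrays ended those of atrophy genes (0.0645 without 5-day replicate 2), inflammatory genes (up to 0.0695, 5-day replicates 2 and 4) and brown adipocyte markers (0.0531, 42-day replicate 4). They also ended those of endothelial markers (up to 0.217, 5-day replicates 1, 2 and 4 and 42-day replicate 1), ER stress (up to 0.139, 7 arrays: chow 1, 3 and 4, 5-day 1 and 2, 42-day 1 and 2) and bone and cartilage markers (up to 0.104, 8 arrays: chow 1 and 4, 5-day 1 to 4, 42-day 1 and 4). Quantile normalization ended the same 8 calls as loess (adjusted p of 0.0683 to 0.325). Leaving out dim genes ended those of branched-chain amino acid catabolism (0.104), atrophy genes (0.332), ER stress (0.343) and endothelial markers (0.474). Ranks and the replicate block ended that of ER stress (0.0504 and 0.0528), and the 3-prime to 5-prime covariate that of bone and cartilage markers (0.0693).

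The last question was how the 5-day and 42-day changes related. Limma's moderated F-test first found 2282 of 18193 genes that differed between any of the 3 groups. Relative to chow, 110 genes rose at both times, Fabp3, Acadl and Etfdh among them. In turn, 61 fell at both, Fasn, Acaca, Acly, Elovl6, Scd1, Tkt and Slc25a1 among them. No gene passed limma's test in opposite directions. Lists drawn independently would share 6.17 and 13.8, and 100 simulations of unchanged groups that used the same chow arrays gave 0. The simulations hold no effects and the independent lists no shared arrays, so neither gives the number expected without a shared change. Another 521 genes passed only at 5 days, of which 146 also passed the test between the times. A further 840 passed only at 42 days, of which 377 did. Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.476, below the simulated mean of 0.5 that shared chow arrays alone gave. Their covariance was 0.00994, against 0.00288 simulated. With separate chow arrays for each time, in 6 splits, the correlation averaged 0.264 (0.0764 to 0.464) and the covariance 0.00613 (0.00216 to 0.00976). The changes had the same sign in 60.1% of genes, against 66.6% simulated and 54.2% (46% to 62.8%) with separate chow arrays. The 171 shared genes became 6 and 42 without 5-day replicates 2 and 4. They became 82, 35 and 83 without chow replicates 1, 3 and 4, and 79, 54, 56 and 52 without 42-day replicates 1 to 4. The F-test count was 736 without 5-day replicate 2 and 735, 874, 1349 and 962 without 42-day replicates 1 to 4.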

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

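Cyclic loess, both covariates, the liver and tendon lists, the leave-one-out spread of the adipocyte test, the folds after loess and the splits in fits of 8 arrays were chosen after the results were seen.

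Of 18 fatty acid synthesis transcripts 6 fell at 5 days and 9 at 42 days (adjusted p = 0.46 and 0.468 for the list with an estimated correlation), while the adipocyte marker mean was 9.02 ± 0.16 at 5 days against 9.61 ± 0.39 on chow and Adipoq was at -1.05 and -0.84, so fewer white or brown adipocytes in the samples is a candidate explanation. With the white adipocyte marker mean as a covariate, the median change of the 6 members called at both times went from -1.12 to -0.56 at 5 days (50.3% left) and from -1.11 to -0.66 at 42 days (59%), and 4 and 6 of the 6 intervals excluded 0. The 50% that had been set beforehand as the bound against this explanation was met by 50.3%, but not beyond its spread, since leaving out single arrays gave 39.4% to 72.5% and 43.8% to 76.4%, lowest without 42-day replicate 2; that spread was added after the value was seen. With Ucp1, Cidea and Otop1 as brown adipocyte markers, 34.3% was left at 5 days (32.1% to 45.4%, median change -0.39) and 52.7% at 42 days (44.1% to 65.3%, median change -0.59). Of all 10 measured brown markers, 7 were higher at 42 days (median 0.069, camera, adjusted p = 0.464). Ucp1 (-1.05) and Cidea (-1.27) were among the 3 lower ones, and the mean of the 10 was -0.18. Slc27a2, also known from liver, was among the 7, so that count does not bear on brown adipocytes alone. A lower share of adipocytes and a lower level within the cells, muscle fibres or others, cannot be told apart, because the markers differ between the diet groups. The time on the diet and the age of the mice stay open, as untested.

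The 8 largest rises at 42 days were liver transcripts, with Alb at 11.87 ± 0.59 and Apoa1 at 10.23 ± 0.73 against 9.68 ± 0.39 and 8.42 ± 0.28 on chow (log2, SD, n = 4). RNA of liver in the muscle samples is a candidate source: in a list of liver genes written before their values were seen, the 12 bright ones went with Alb within groups at a median correlation of 0.766 (0.116 to 0.95, 10 over 0.5), and of 1000 random lists 0 were as high (highest 0.305). The random lists were matched on signal alone. The values therefore show that these transcripts varied together, and not where they came from. A signal-dependent shift between arrays is argued against by its size, since the median change by signal bin ran only from 0.023 to -0.051. Cyclic loess left 101% of the median rise of the 8 genes (1.83 before, 1.84 after, 100% to 101% without single arrays). Loess could hardly have lowered rises of this size given so small a trend, so that result adds little. Whether the diet raised these transcripts in muscle itself was not tested, so it and the age of the mice stay open.

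Between 42 and 5 days bright genes were lower and dim genes higher, from 0.088 in signal bin 3 to -0.12 in bin 9. After cyclic loess 363 genes were called, a number 23.4% the size of the 1550 before, and 319 of the 1550 were still called. That percentage was under the 50% set beforehand for a signal-dependent shift between arrays. The median size of the 1550 changes went only from 0.26 to 0.20 (72.6% left, quartiles 62.9% and 86.8%), however, and 1004 stayed within 1.5 times. Loess flattens a trend with signal by construction and would also remove a broad change of the RNA itself, so the shift and such a change cannot be told apart. The mean 3-prime to 5-prime difference differed by -0.13 between these groups. The changes it predicts from the spread within groups correlated with those seen at -0.0445 across genes. A negative correlation had been set beforehand as the bound against RNA integrity, and it was met. The value lay inside the -0.545 to 0.579 of 1000 permutations, which were not part of that bound. The test therefore cannot decide whether RNA integrity contributed. The time on the diet and the age of the mice stay open, as untested, and differ together between these groups, so they cannot be told apart.

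Other splits of the arrays into groups of the same sizes were counted for each total, by regrouping the 8 arrays compared in the fit of all 12, with the third group kept. For the genes changed, the real split alone gave as many, 1 of 35 splits each time. The counts were 692 against a highest other of 27 at 5 days and 1011 against 2 at 42 days. They were 1550 against 51 between the times, and 2282 against 2 for the F-test in 100 drawn splits. With 4 against 4 arrays, 1 of 35 is the smallest share possible, and mixed splits carry a group difference into the spread. The real counts thus stood apart, but chance is not excluded. In fits of the 8 arrays alone the real split also gave the most: 7 at 5 days, where the next had 1, 772 at 42 days (next 0) and 1624 between the times (next 19); at 5 days the larger count thus needed the 42-day arrays in the fit. At an unadjusted p under 0.05 by limma in those fits, the real split gave 3917 genes at 5 days (highest other 2594). It gave 3984 at 42 days (highest other 1897) and 5916 between the times (highest other 2861). For the gene lists chance cannot be excluded either: 5 of 35 splits gave as many at 5 days (15, highest other 16), 27 at 42 days (8, highest other 16) and 4 between the times (13, highest other 14).

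Among 288 groups of 4 arrays for 96 named genes, 11 held 1 array far from the other 3, against about 1 in 20 by chance: Adipoq, chow replicate 4 (12.91), Cd36, 42-day replicate 1 (12.21), Chad, chow replicate 1 (8.62), Col5a2, chow replicate 4 (10.32), Cry2, chow replicate 1 (10.32). The others were Hk2, chow replicate 4 (13.40), Ier5, chow replicate 1 (9.14), Opa1, chow replicate 1 (11.92), Ppargc1a, 5-day replicate 4 (10.58), Saa2, 42-day replicate 2 (6.60) and Zbed6, 42-day replicate 4 (8.03), as log2 signal.

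The 42-day change differed from the 5-day change in 1550 genes by limma's test of the difference. Higher at 42 days were Acadl (0.26), Alb (1.91), Apoa1 (1.48), Bhmt (1.12), Cd36 (0.39), Cd3e (0.23), Comp (0.34), Elovl3 (0.27), Fabp1 (1.53), Fabp3 (0.21), Fmod (0.62), Mug1 (1.29), Mup3 (1.01), Saa3 (0.22), Serpina1b (1.58), Serpina1c (1.37), Slc27a1 (0.24) and Slc27a2 (0.41), as log2 fold changes of 42 against 5 days. Lower were Adamts1 (-0.40), Alpl (-0.18), Atf3 (-1.05), Btg2 (-0.58), Crebbp (-0.57), Cry2 (-0.25), Eif4ebp1 (-0.33), Fos (-1.28), Fosl2 (-0.48), Gmps (-0.56), Hk2 (-0.22), Hspa5 (-0.25), Ier5 (-0.38), Insr (-0.24), Irs2 (-0.62), Malat1 (-1.04), Mmut (-0.31), Opa1 (-0.22), Pdpk1 (-0.27), Per1 (-0.30), Pik3ca (-0.23), Ppard (-0.27), Ppargc1a (-0.44), Rictor (-0.26), Tmem252 (-0.31), Vwf (-0.33) and Zbed6 (-0.56). With the mean of probe sets 29 of these 45 calls ended.

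Lists whose changes differed between the times had adjusted p by camera of 0.00139 for fatty acid oxidation, 0.000548 for insulin signalling, 0.000203 for mitochondrial biogenesis and dynamics, 0.00258 for branched-chain amino acid catabolism, 0.0129 for atrophy and glucocorticoid-induced genes, 0.00258 for circadian clock, 0.000406 for immediate early genes, 0.0487 for ER stress and integrated stress response, 0.0243 for inflammatory cytokines and NF-kB pathway, 0.0078 for brown adipocyte markers, 0.00124 for lymphocyte markers, 0.0391 for endothelial markers and 0.0487 for bone and cartilage markers. None of the 13 passed with an estimated correlation (adjusted p of 0.612 to 0.66), and cyclic loess ended 8 of the calls.

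Of the 9160 probe sets with no gene symbol, which the comparisons do not use, 267 (44 rose, 223 fell), 439 (126 rose, 313 fell) and 343 (209 rose, 134 fell) passed limma's test at 5 days, at 42 days and between the times.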

How the results depend on the processing

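Cyclic loess and both covariates were chosen after seeing the data, and the cause was not tested where a value moved, except that fewer arrays or genes were used where the setting says so. Counts of changed genes are given in the order 5 days, 42 days, between the times and F-test, against 692, 1011, 1550 and 2282. With the replicate block they were 880, 1051, 1778 and 2413, with 15, 8 and 12 lists and 199 shared genes. The block ended the named calls of Alpl and Hadha at 5 days (limma, adjusted p = 0.0529 and 0.0539). At 42 days it ended those of Ccn2 (0.0565), Chad (0.0567) and Ndufs1 (0.0743), and between the times those of Comp (0.0559) and Alpl (0.0575). Quantile normalization gave 208 at 5 days, 371 between the times, 1354 by F-test and 87 shared genes, and cyclic loess 207, 363, 1225 and 77. Centring moved the median of all genes by less than 0.1 and gave 1343 at 5 days (84.6% rose, against 42.1%), 3474 between the times (7.34% against 32.3%) and 3748 by F-test. The most variable probe set gave 1148, 2628 and 3722 by F-test, 4 lists between the times and 495 shared genes, the mean of probe sets 529 between the times, and every probe set 1445, 3953, 2692 and 5829. An adjusted p under 0.1 gave 2073, 1872, 3682 and 4678, array weights 159 at 5 days and 67 shared genes, and a fit of the 8 arrays 7 at 5 days. The 3-prime to 5-prime covariate gave 297, 10, 0 (limma, 3955 at an unadjusted p under 0.05) and 24, with 5 shared genes, and the adipocyte covariate 33, 167 and 1390 by F-test, with 10. Without single arrays the counts ran from 6 (without 5-day replicate 2) to 790 (without 5-day replicate 1) at 5 days, 228 (without chow replicate 3) to 1079 (without chow replicate 1) at 42 days, 0 (without 42-day replicate 1) to 1972 (without chow replicate 3) between the times (0 by limma, with 4107 unadjusted), 735 (without 42-day replicate 1) to 2242 (without 5-day replicate 1) by F-test and 6 (without 5-day replicate 2) to 168 (without 5-day replicate 3) for shared genes. Lists past the test numbered 0 at each time with an estimated correlation (2 unadjusted each), 3, 5 and 4 with fry, and, between the times, 8 without the dimmest genes, 5 after quantile normalization and 7 after cyclic loess; without single arrays they ran from 13 (without chow replicate 4) to 16 (without chow replicate 1), 7 (without chow replicate 4) to 14 (without chow replicate 2) and 8 (without 5-day replicate 2) to 14 (without 5-day replicate 3). Other settings left these counts within 1.5 times. Opa1 turned direction at 42 days against chow (0.46 with the mean of probe sets, 0.85 with the most variable) and against 5 days (0.095 and 0.37), Rictor against 5 days (0.012 with the mean), and Slc2a4 (0.25 and 0.52) and Ucp3 (0.47 with the most variable) against chow. The interferon list turned at 5 days (camera, adjusted p = 0.619 without chow replicate 4 and 0.153 with the adipocyte covariate). Over left-out arrays 0.619 was its highest and 0.00103 (without chow replicate 1) its lowest. The adipocyte list turned with the adipocyte covariate (0.934 at 5 days, 0.861 at 42 days) and with the 3-prime to 5-prime covariate (0.607 at 42 days). The adipocyte covariate is the mean of that list itself, so it removes the list's change by construction. No named call turned direction under quantile normalization, centring or cyclic loess, and signal over background limits what dim probe sets can show.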

Other observations

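Lists of tendon and liver transcripts were chosen after Fmod, Comp and Alb had been seen, so their tests describe the same data. Of 8 measured tendon transcripts whose values had not been seen, 4 rose at 42 days against chow and all 8 were higher, with a median of 0.33 (limma's camera, adjusted p = 3.74e-09 over 12 tests, and adjusted p = 0.053 with an estimated correlation). Of 11 seen before, 9 rose. Against 5 days 3 of the 8 rose (adjusted p = 0.00164, and adjusted p = 0.131 with an estimated correlation). At 5 days against chow 7 of 8 were higher (adjusted p = 0.00554, and adjusted p = 0.157 with an estimated correlation). Of 35 liver transcripts not seen before, 12 rose at 42 days, 33 were higher and the median was 0.40 (adjusted p = 5.63e-18, and adjusted p = 0.113 with an estimated correlation). Of 19 seen before, 14 rose. Against 5 days 17 of the 35 rose and all 35 were higher (adjusted p = 6.44e-15, and adjusted p = 0.113 with an estimated correlation). At 5 days 1 fell and the median was 0.017 (adjusted p = 0.869).

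Of the 36 lists, 15 were not past camera's test in any comparison: PPAR target genes, cholesterol synthesis, sphingolipid synthesis and turnover, glycolysis and glycogen, fast fibre genes, myogenic regulators and embryonic or denervation genes, heat shock proteins, antioxidant defence, secreted muscle factors, proliferation, macrophage and monocyte markers, neutrophil markers, Schwann cell markers, erythroid markers and keratinocyte and epithelial markers. Their smallest adjusted p in any comparison ran from 0.134 to 0.857.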
